A study of Homo sapiens with 66 samples.

How the data were processed

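CUT&RUN libraries of BRD4 (4 groups of 2) and of the HA-tagged fusion in non-crosslinked DMSO cells (2 libraries) were analysed, and the other 56 samples of the series were not analysed here. Per the submitters' processing notes the reads were aligned to hg19, and the notes name Trimmomatic 0.32, Bowtie2, Genrich 0.6.1, DiffBind, DESeq2 and deepTools without saying what each was used for. The BRD4 values are raw counts per region as deposited by the authors, with no normalization. How those regions were chosen, whether duplicate reads were removed and whether the start coordinate counts from 0 or 1 is not given in the sources used here, and BRD4 coordinates are printed as deposited. If the regions were selected on some of these libraries, their choice can favour one direction of change. The HA peaks were called with MACS2 at a q threshold of 0.01 on 2 merged libraries, per the labels and the deposited file's name. The authors' peak list gives a fold enrichment (a ratio), a -log10 p, a -log10 q-value, a score and a summit for each peak, and the control behind the fold is not given in the sources used here. HA peak positions were converted to count from 1.

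The columns of the count table carry a treatment, a time and a letter A or B. They were assigned to groups by treatment and time, and the letters were not matched to the replicate numbers of the labels. Regions with too few reads were removed by the default filter of edgeR (filterByExpr, 551 of 16173 removed, 15622 tested). TMM factors, dispersions and quasi-likelihood F tests with robust estimation came from edgeR 4.0.16 in R 4.3.3, with all 8 libraries in one fit of 4 groups and 4 residual degrees of freedom. A region was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. The common dispersion was 0.0068. CPM values use the TMM-scaled totals, and log2 CPM for single libraries used a prior count of 2. The standard error of a log2 change was taken as its size divided by the square root of the F statistic.

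A region had an HA peak if they shared at least 1 base (GenomicRanges 1.54.1), and its HA strength was the highest fold enrichment among its peaks. Regions with a peak were ranked into 5 bins of equal size. The set of regions with a peak was tested against the others with camera from limma 3.58.1, at a preset correlation of 0.01 and again with an estimated correlation. An exact permutation of 2 libraries against 2 cannot give a two-sided p below 0.33, so it was not run. Regions are named by position because no annotation of hg19 was at hand. The planned gene lists, distances to transcription starts and sequence motifs were therefore not run. The rule for naming, fixed before the data were examined, took at most 5 regions per direction and comparison by smallest p, among those called with an absolute log2 change of at least 0.58 and with both libraries of one group on the same side of both libraries of the other, and the 10 HA peaks with the highest fold enrichment.

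The steps were tested on simulated data, with counts drawn from the means and totals of the real libraries and 200 regions changed per comparison. At 2 h, 4 h and 24 h the test recovered 8.54%, 13.6% and 10.2% of 1.5-fold changes, 35.6%, 33.8% and 28.6% of 2-fold changes and 88.1%, 80.3% and 84.4% of 4-fold changes, with 2, 7 and 3 false calls, over 15484, 15504 and 15485 regions. Changes of 1.5-fold and 2-fold were thus mostly missed in the simulation. It gave all groups the trended dispersion of edgeR, so it holds no wider spread in DMSO. With more changed regions than the 200 simulated, the adjusted p is easier to pass. The rates and false calls therefore need not hold for the real libraries. Alternatives fixed before the data were examined covered the scaling (RLE, upper-quartile or no factors), the filter on low counts, DESeq2 1.42.0 and limma-voom in place of edgeR, each library left out, only the compared groups in the fit, the thresholds, and the definition of an HA peak and of the regions it is compared with. Trended scaling, TMM factors from regions without an HA peak, a block on the column letter, limma-voom with a weight per group, DESeq2 with the common dispersion of edgeR and the use of 1 DMSO library per comparison were added after seeing the data. Overlaps between comparisons with the same DMSO libraries were set against 20 simulations of unchanged groups.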

Results

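The series measured protein binding to chromatin in Rh30 cells by CUT&RUN, in which an antibody directs a nuclease to the protein and the released DNA is sequenced. Rh30 is an established alveolar rhabdomyosarcoma line driven by PAX3-FOXO1, a fusion of the DNA-binding domains of PAX3 with the activation domain of FOXO1. In the engineered cells the fusion carries an FKBP tag, which the degrader dTAG47 (500 nM) links to the cell's protein disposal machinery, and the carrier DMSO served as the control. The labels describe 66 samples in 33 groups of 2 libraries each. The comparisons below rest on 10 of these libraries, namely 8 for BRD4 and 2 for the HA epitope of the tagged fusion in DMSO, and the other 56 are not analysed here. BRD4 is a bromodomain protein that binds acetylated histones at active enhancers and promoters. Its 8 libraries form 4 groups of 2, treated with DMSO or with dTAG47 for 2 h, 4 h or 24 h. Their table counts reads in 16173 regions, of which 16165 are 400 bases wide, and 15622 regions had enough reads to be tested.

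The BRD4 libraries are distinguished in the table by the letters A and B. The reads counted in all regions were 253265 and 592616 for DMSO libraries A and B, 317314 and 558568 at 2 h, 465477 and 677799 at 4 h, and 329036 and 539433 at 24 h. These totals cover the listed regions, so the sequencing depth of each library is unknown. The median region held 12 to 32 reads per library, and a single read equalled between 1.44 and 4.09 CPM, the counts scaled to a common total per library. Libraries of one group differed from each other by more than counting noise, with a chi-square per degree of freedom of 1.45 for the DMSO pair, 1.14 at 2 h, 1.14 at 4 h and 1.06 at 24 h. The labels do not say whether the libraries of a group came from separate cultures, so the spread between them may be technical. The p-values rest on a spread pooled over the 4 groups and shared across regions. Its median prior weight was 140 degrees of freedom, against 4 residual ones from the libraries of a region. The p-values therefore do not follow the wider spread of the DMSO pair, which enters each comparison with DMSO.

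The HA peak list gives where HA signal was called in DMSO, and its peaks were taken to mark the tagged PAX3-FOXO1. No HA library from untagged or dTAG47-treated cells was analysed here to test this. The list held 44740 peaks on hg19, called by the authors on the 2 merged libraries, so its values have no replicate error. Peak widths ran from 244 to 3591 bases with a median of 608. The authors' fold enrichment had a median of 5.12 and a highest value of 34.3. The peak of highest fold enrichment lay on chromosome 9 from 69710695 to 69711359. Next came peaks on chromosome 10 at 135490704 to 135491431 (31.2-fold) and on chromosome 9 at 66970971 to 66971655 (30.7-fold). The last of these had a -log10 p of 19253, against 1020.8 for the peak of highest fold enrichment. Whether signal other than fusion binding raised the most enriched peaks was not tested. The remaining 7 of the 10 most enriched peaks began on chromosome 5 at 70575613, chromosome 9 at 67320374, chromosome 17 at 19091075, chromosome 12 at 38543606, chromosome 6 at 119558561 and chromosome 2 at 132997272 and 92269007. Those on chromosomes 5 and 17 overlapped no BRD4 region. No annotation of hg19 was at hand, so no peak or region is assigned to a gene.

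Most BRD4 regions coincided with an HA peak. Of the 16173 regions, 13951 (86.3%) overlapped an HA peak by at least 1 base, against 2.24% to 2.54% after the regions were shifted by 100 or 200 kb. Shifted regions need not lie where any protein is bound, and no peak list of another protein was compared. The contrast therefore does not show that the overlap is particular to the fusion. The reverse share was smaller, since 13721 of the 44740 HA peaks (30.7%) overlapped a BRD4 region. Overlap was more frequent among strong peaks. When peaks were ranked by fold enrichment into 5 bins, 50.5% of the strongest bin and 13.9% of the weakest bin overlapped a BRD4 region. The median distance from the midpoint of a BRD4 region to the summit of an overlapping HA peak was 113 bases.

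The first comparison asked where BRD4 binding changed after 2 h in dTAG47. BRD4 was lower than in DMSO at 706 regions and higher at 84 (edgeR quasi-likelihood test, adjusted p under 0.05, n = 2 per group). The lower regions had a median fold change of 2.14, and 422 of them fell at least 2-fold. Among the lower regions, 704 of 706 overlapped an HA peak, and 529 (74.9%) lay in the strongest of 5 bins of HA enrichment. Among the higher regions, 61 of 84 (72.6%) overlapped an HA peak and 6 lay in the strongest bin. Of all 15622 tested regions, 86.8% overlapped an HA peak and 2711 lay in the strongest bin. A region on chromosome 2 at 46560132 to 46560532 had the smallest p. It fell from 232 ± 13.3 CPM in DMSO to 46.3 ± 14.2 CPM (SD, n = 2), a log2 change of -2.38 ± 0.24 (SE, adjusted p = 1.7e-13). BRD4 on chromosome 9 at 133536450 to 133536850 fell from 326 ± 44.8 to 93.6 ± 8.40 CPM. Regions starting at 89609400 on chromosome 16, 27378186 on chromosome 17 and 36070970 on chromosome 1 had log2 changes of -1.39, -1.62 and -1.82. All 5 of these regions overlapped an HA peak, with enrichments from 5.09-fold to 17.2-fold. Of the regions that rose, the one with the smallest p, on chromosome 7 at 150676374 to 150676774, had 83.3 ± 48.4 CPM in DMSO and 195 ± 14.0 CPM at 2 h, and its DMSO libraries differed from each other (49.1 and 118 CPM). Rises were also called on chromosome 12 at 48222616, chromosome 16 at 30933829, chromosome 6 at 30654980 and chromosome 17 at 21314286, with log2 changes of 1.31, 0.72, 1.33 and 1.11. DESeq2 called 32 lower regions and 0 higher, so none of the 5 named rises passed with it. Without DMSO library B the counts were 188 and 12, without library A of the 2 h group 416 and 39, and without its library B 272 and 23, while 52 regions were higher without DMSO library A and 52 with only the DMSO and 2 h groups in the fit.

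**Figure D1:**
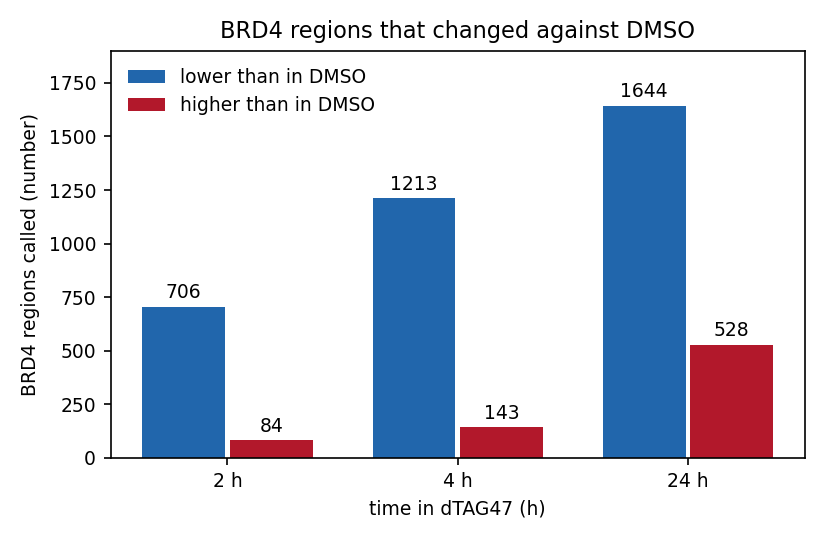
Number of BRD4 regions called lower (blue bars) or higher (red bars) than in DMSO (vertical axis, number of regions) after 2, 4 and 24 h in dTAG47 (horizontal axis), by edgeR at an adjusted p under 0.05 among 15622 tested regions, n = 2 libraries per group. Lower regions outnumber higher ones at each time, from 706 against 84 at 2 h to 1644 against 528 at 24 h.

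At 4 h in dTAG47, BRD4 was lower than in DMSO at 1213 regions and higher at 143. The lower regions had a median fold change of 2.15, and 719 fell at least 2-fold. An HA peak overlapped 1205 of the 1213 lower regions, and 852 (70.2%) lay in the strongest HA bin, against 115 and 5 of the 143 higher regions. The region on chromosome 17 at 27378186 to 27378586 fell from 321 ± 19.8 CPM in DMSO to 48.5 ± 9.38 CPM (SD, n = 2), a log2 change of -2.77 ± 0.20 (SE, adjusted p = 1.9e-23 by edgeR). Falls at regions starting at 89609400 on chromosome 16, 36070970 on chromosome 1, 47629716 on chromosome 17 and 44628339 on chromosome 6 measured -2.02, -2.67, -1.99 and -3.04 on the log2 scale. The region on chromosome 16 at 30933829 to 30934229 rose from 188 ± 23.3 to 328 ± 11.4 CPM, and the one on chromosome 1 at 41174840 to 41175240 from 83.4 ± 8.0 to 171 ± 25.3 CPM. The other named rises started at 7789019 on chromosome 17, 17003107 on chromosome 11 and 32803868 on chromosome 1, with log2 changes of 0.67, 1.34 and 1.12. With DESeq2, 191 regions were lower and 0 higher, so these 5 rises did not pass there. The counts were 488 and 36 without DMSO library B, 785 and 48 without library A of the 4 h group, and 685 and 57 without its library B.

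At 24 h, the latest time, BRD4 was lower than in DMSO at 1644 regions and higher at 528. The lower regions had a median fold change of 2.39, 1167 of them fell at least 2-fold, and 1598 overlapped an HA peak. The share in the strongest HA bin was 56.1%. The region on chromosome 16 at 89609400 to 89609800 had the smallest p and fell from 499 ± 5.09 CPM in DMSO to 79.9 ± 19.0 CPM (SD, n = 2), a log2 change of -2.59 ± 0.18 (SE, adjusted p = 2.8e-25 by edgeR). The region on chromosome 6 at 44628339 to 44628739 fell from 176 ± 17.2 to 7.27 ± 2.53 CPM, with 46 and 92 reads in the DMSO libraries and 3 in each 24 h library. Regions at 27378186 on chromosome 17, 36070970 on chromosome 1 and 18335485 on chromosome 2 had log2 changes of -3.14, -3.32 and -2.14. Among the 528 higher regions, 413 (78.2%) overlapped an HA peak, below the 86.8% of all tested regions, and 21 lay in the strongest bin. On chromosome 7, the region at 150676374 stood at 244 ± 9.09 CPM, a log2 change of 1.36 ± 0.20 (SE) from DMSO (adjusted p = 6.5e-08 by edgeR). A region on chromosome 1 at 55024132 to 55024532, without an HA peak, rose from 22.1 ± 3.50 to 86.5 ± 7.01 CPM. Named rises also began on chromosome 3 at 13521159, chromosome 1 at 41174840 and chromosome 14 at 95981458, with log2 changes of 1.06, 1.12 and 1.27. DESeq2 called 419 regions lower and 7 higher, leaving out DMSO library B gave 708 and 130, leaving out library A of the 24 h group gave 247 higher, and leaving out its library B gave 999 lower and 215 higher.

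The division between lower and higher calls depended on how the libraries were scaled to each other. Lower regions made up 89.4% of the calls at 2 h, 89.5% at 4 h and 75.7% at 24 h with TMM factors. With table totals alone the counts were 573 lower and 148 higher at 2 h (79.5% lower), 962 and 323 at 4 h (74.9%), and 1384 and 864 at 24 h (61.6%). Upper-quartile factors gave 581 and 121, 971 and 291, and 1389 and 817. With TMM factors taken from the regions without an HA peak, the counts were 1307 and 25 at 2 h, 2050 and 20 at 4 h, and 2806 and 103 at 24 h. The median log2 change of all tested regions was 0.01 at 2 h, 0.02 at 4 h and 0.02 at 24 h with TMM, 0.07, 0.12 and 0.11 with totals alone, and -0.18, -0.21 and -0.24 with factors from the regions without an HA peak. Each change is therefore relative to the bulk of the counted regions.

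Lower calls recurred between times more often than independent lists would share them. Of the 706 regions lower at 2 h, 633 were also lower at 4 h and 586 at 24 h, where independent lists would share 54.8 and 74.3. The lower lists of 4 h and 24 h shared 910 regions, against 128 for independent lists. All 3 times had 554 lower regions in common, out of 1988 lower at any time, and no region was called in opposite directions. Of the 84 regions higher at 2 h, 16 were also higher at 4 h and 27 at 24 h, where independent lists would share 0.77 and 2.84. The higher lists of 4 h and 24 h shared 64 regions, against 4.83. In all, 10 regions were higher at all 3 times, of 658 higher at any. The regions lower at 2 h had a median log2 change of -1.10 at that time, -1.16 at 4 h and -1.29 at 24 h. The comparisons share their DMSO libraries. Log2 changes correlated across regions, which are not independent replicates, with r = 0.75 between 2 h and 4 h, 0.63 between 2 h and 24 h and 0.73 between 4 h and 24 h, whereas 20 simulations of unchanged groups gave mean values of 0.56, 0.52 and 0.56. The covariances of 0.20, 0.21 and 0.27 exceeded the simulated 0.069 in each pair. The simulation gave all groups the same dispersion, so it holds no wider spread in DMSO and can understate what shared libraries add. In a check chosen after seeing the data, the comparisons shared no DMSO library, as one used DMSO library A alone and the other library B alone. With library A in the earlier comparison, or B in brackets, the covariances were 0.13 (0.13) between 2 h and 4 h, 0.13 (0.14) between 2 h and 24 h and 0.18 (0.20) between 4 h and 24 h. The lower lists then shared 125 (252), 123 (315) and 318 (424) regions, against 13.1 (21.9), 18.5 (31.7) and 48.1 (49.3) for independent lists. The higher lists shared 1 (2), 2 (2) and 6 (4) regions, against 0.10 (0.12), 0.31 (0.43) and 0.93 (1.08). Part of the overlap between lists made with both DMSO libraries may therefore come from the shared libraries.

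BRD4 loss was graded with the strength of the HA peak. Regions with no HA peak had a median log2 change of 0.19 at 2 h, 0.23 at 4 h and 0.26 at 24 h. In the strongest HA bin, which covers enrichments from 8.71-fold to 30.7-fold, the medians were -0.37, -0.44 and -0.49. Computed from the log2 CPM of each dTAG47 library against the DMSO mean, with a prior count that draws changes towards 0, the medians of that bin were -0.35 and -0.33 at 2 h, -0.40 and -0.39 at 4 h, and -0.45 and -0.42 at 24 h. At 24 h the medians of the 5 bins from weakest to strongest were 0.17, 0.13, 0.05, -0.07 and -0.49. Called losses made up 19.5%, 31.4% and 34.0% of the strongest bin at 2, 4 and 24 h, against 0.097%, 0.39% and 2.23% of the regions with no HA peak. Across the 13556 tested regions with an HA peak, HA enrichment and log2 change had a Spearman's rho of -0.35 at 2 h, -0.39 at 4 h and -0.36 at 24 h, with regions not being independent replicates. The sign of the medians in the weaker bins depends on the scaling. With factors from the regions without an HA peak, the weakest bin had a median of -0.08 at 24 h and the strongest -0.75, while their difference of -0.66 was the same as with TMM.

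**Figure D2:**
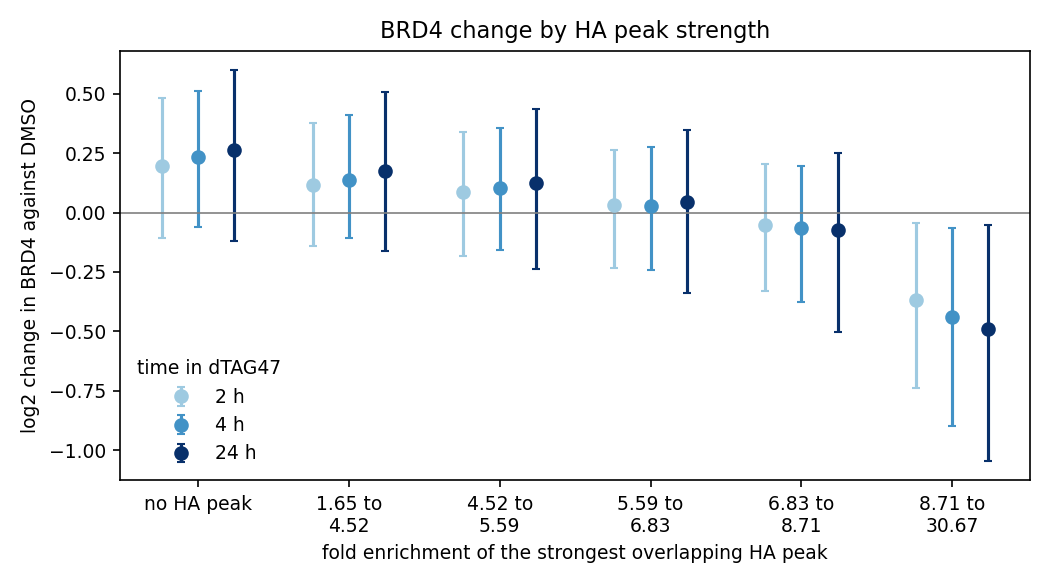
Log2 change in BRD4 against DMSO (vertical axis) for tested regions with no HA peak and for 5 equal-sized bins of the fold enrichment of the strongest overlapping HA peak (horizontal axis), after 2, 4 and 24 h in dTAG47. Points are medians over regions and bars span the 25th to 75th percentile. With TMM scaling the medians descend from 0.26 without an HA peak to -0.49 in the strongest bin at 24 h, and factors from the regions without an HA peak turn the weakest bin's median to -0.08.

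Regions with any HA peak stood lower than the 2066 tested regions without one by a median log2 change of -0.21 at 2 h, -0.24 at 4 h and -0.28 at 24 h. From the log2 CPM of each dTAG47 library the differences were -0.22 and -0.18, -0.25 and -0.21, and -0.27 and -0.22. The camera test of limma gave an adjusted p = 1.1e-05 at 2 h, 8.0e-07 at 4 h and 7.2e-06 at 24 h, adjusted over 6 comparisons of times. With an estimated correlation the camera test gave an adjusted p = 0.0070 at each time. The estimate of 0.0052 was below the preset 0.01, so a higher correlation is not what raised the p. The smaller p-values at the preset correlation lean on the number of regions, which are not independent replicates. The same difference did not pass between 2 h and 4 h (-0.054, adjusted p = 0.19 by camera) or between 4 h and 24 h (-0.024, adjusted p = 0.47 by camera). When a region counted as HA-bound only if it contained the HA summit, the differences were -0.056, -0.0838 and -0.0896 and did not pass (adjusted p = 0.32 at each time by camera, 0.24 with an estimated correlation). When it had to contain at least 0.5 of the HA peak, the differences turned to 0.13, 0.12 and 0.13 and passed in that opposite direction (adjusted p = 0.0043, 0.0043 and 0.016 by camera, and 0.0035, 0.0035 and 0.0046 with an estimated correlation). Both stricter rules put the remaining regions with an HA peak into the comparison group. That group then held 5564 regions under the summit rule and 9738 under the other, in place of 2066. Neither rule therefore compares regions with and without an HA peak. In the weakest HA bin 66.7% of the regions contained at least 0.5 of the peak and in the strongest 20.5%, as the median peak widths were 504 and 1010 bases against the regions' 400. Among regions with a mean of at least 50 reads the 24 h difference was -0.12 and did not pass.

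The comparisons between times asked which BRD4 changes came late. The labels give a single DMSO group for BRD4 and no time for it. Changes between times therefore cannot be told apart from effects of time in culture. Between 2 h and 4 h, edgeR called 0 regions lower and 0 higher, with 616 and 418 at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. From 4 h to 24 h, BRD4 was lower at 134 regions and higher at 33. Of the 134, 109 were also lower at 24 h than in DMSO, in a comparison that uses the same 24 h libraries. Already lower at 4 h were 12, against 10.4 for independent lists. Both lists use the 4 h libraries, so a chance high count at 4 h can give a later fall and hide an earlier one. The near match therefore does not show that late and early falls are unrelated. An HA peak overlapped 120 (89.6%), near the 86.8% of all tested regions. On chromosome 17 at 77049323 to 77049723, BRD4 measured 163 ± 33.9 CPM in DMSO, 125 ± 21.4 CPM at 4 h and 40.1 ± 5.42 CPM at 24 h (SD, n = 2), a log2 change of -1.58 ± 0.26 from 4 h to 24 h (SE, adjusted p = 1.3e-04 by edgeR). The other named late falls started at 94886198 on chromosome 8, 59894658 on chromosome 11, 75086369 on chromosome 14 and 56944649 on chromosome 16, and measured -2.16, -2.56, -1.66 and -1.08. Of the 33 regions higher at 24 h than at 4 h, 13 were higher at 24 h than in DMSO. Lower at 4 h than in DMSO were 8, against 2.56 for independent lists. These comparisons share the 4 h or the 24 h libraries, so a chance low count at 4 h can give both a fall and a later rise. The regions named next were chosen by the p of the rise. On chromosome 17, the region at 47629716 to 47630116 went from 310 ± 10.1 CPM in DMSO to 78.1 ± 0.37 CPM at 4 h and back to 177 ± 5.25 CPM at 24 h. On chromosome 7, the region at 30952726 to 30953126 fell from 368 ± 23.2 CPM to 227 ± 14.8 CPM at 4 h and measured 405 ± 26.7 CPM at 24 h, and the one at 2535494 to 2535894 measured 359 ± 1.45, 102 ± 15.1 and 203 ± 33.4 CPM at the same points. Regions on chromosome 1 at 55024132 and on chromosome 17 at 42172933 rose by 1.25 and 0.91 on the log2 scale from 4 h to 24 h. DESeq2 called 0 regions in either direction here, and limma-voom called 51 lower and 19 higher. Leaving out library A or B of the 4 h group gave 21 and 4 or 23 and 5 regions lower and higher, leaving out library A or B of the 24 h group gave 16 and 5 or 14 and 2, and leaving out DMSO library A or B gave 50 or 52 higher.

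**Figure D3:**
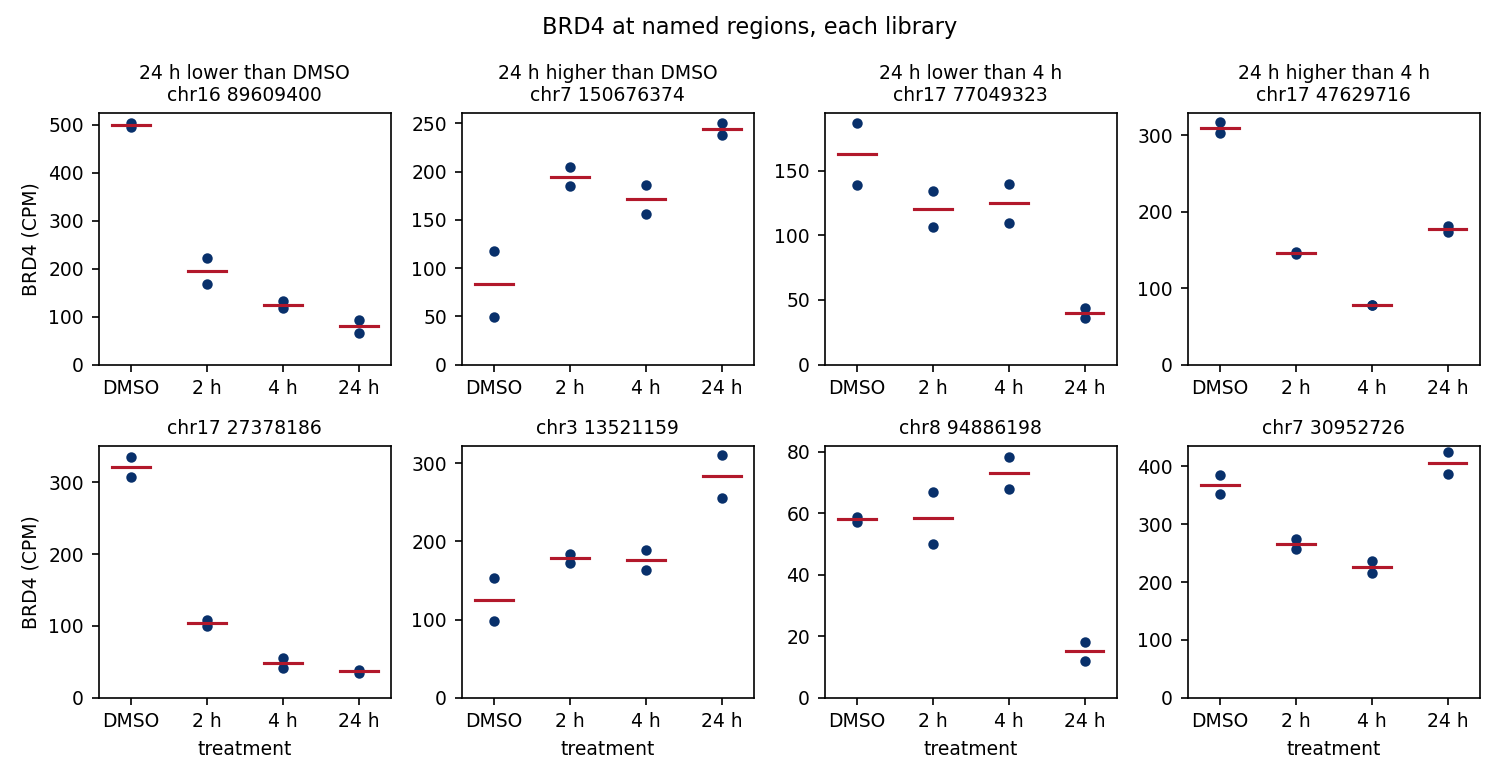
BRD4 counts scaled to a common total per library (CPM, vertical axes, each starting at 0) in each library (dots, n = 2) and their mean (red line) in DMSO and after 2, 4 and 24 h in dTAG47 (horizontal axes), for the pair of regions with the smallest p among those lower or higher at 24 h than in DMSO and lower or higher at 24 h than at 4 h. The region at 89609400 on chromosome 16 drops from 499 to 79.9 CPM by 24 h, whereas the one at 47629716 on chromosome 17 drops to 78.1 CPM at 4 h and stands at 177 CPM at 24 h.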

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

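Of the tests in this part, those of trended scaling, TMM factors from regions without an HA peak and the contrast of 24 h with 2 h were chosen only after the result was seen.

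The changes from DMSO differed between 4 h and 24 h, by the direct test between those times, at 134 regions with less BRD4 and 33 with more at 24 h. Both counts were 0 with DESeq2. Leaving out a 4 h library gave 21 and 4 (A) or 23 and 5 (B), leaving out a 24 h library 16 and 5 (A) or 14 and 2 (B), and without DMSO library A or B 50 or 52 regions were higher. No technical explanation of these late changes was tested.

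BRD4 fell most at regions with the strongest HA peaks, and the tables argue against 3 technical explanations as the whole cause of the 24 h pattern. A bias with read count would vanish among regions of like count, but the strongest bin still differed from count-matched regions of the weakest bin by -0.64 (log2; -0.60 and -0.57 from the log2 CPM of the 24 h libraries). Lower enrichment of the dTAG47 libraries would vanish once the trend of change with count is removed, but the difference was then -0.66. Chance high counts in DMSO would not show between 24 h and 2 h, where the bins still differed by -0.17 (-0.17 and -0.16 in the 24 h libraries). That covers only the loss after 2 h, and for the strongest bin against all other regions camera gave an adjusted p = 0.0024, or 0.20 with an estimated correlation, so a part played by the DMSO libraries stays open. Loss of BRD4 upon loss of the fusion stays as an untested hypothesis, as no cells without the tag were analysed here to separate it from other effects of dTAG47. Time in culture is not separated either, as the labels give no time for the DMSO group.

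For most of the 528 regions higher at 24 h than in DMSO, whether the call reflects a gain or the scaling cannot be told. With factors from regions without an HA peak 103 of the calls (19.5%) remained, but those factors lower all regions alike, moving the median log2 change of all regions from 0.02 to -0.24, so the drop in calls follows from their choice. With TMM the 528 regions had a median log2 change of 0.95 and a lower quartile of 0.75. A shift of that size thus costs calls but leaves most of these changes above 0. Their sizes are inflated, as the regions were chosen on the same libraries. Totals alone and upper-quartile factors moved the count the other way, to 864 and 817. Dim regions raised by lower enrichment are argued against, as 97.4% of the calls remained once the trend of change with count was removed. No spiked-in reference was used here to decide between the scalings.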

How the results depend on the processing

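Trended scaling, factors from regions without an HA peak, the letter block, the weights per group and the exchanged dispersion were chosen after seeing the data. Counts are lower/higher, and where no cause is named the cause was not tested. Against DMSO, losses outnumbered gains in all settings run. Moved counts at 2, 4 and 24 h were, with totals alone, 148, 323 and 864 higher; with upper-quartile factors 291 and 817 higher at 4 and 24 h; with factors from regions without an HA peak 1307/25, 2050/20 and 2806/103; with DESeq2 32/0, 191/0 and 419/7; with adjusted p under 0.1 200, 319 and 974 higher; with at least 50 reads on average, where fewer regions are tested, 231, 307 and 339 lower and 221 higher at 24 h; and with only the compared groups 52 higher at 2 h. All 419 losses that DESeq2 called at 24 h were edgeR calls. DESeq2 used a median dispersion of 0.074, although its estimate sat at the lower limit for 85.3% of regions, against 0.0068 in edgeR, and gave no adjusted p for 9086 regions at 2 h and 303 at 4 h. With the edgeR dispersion set for all regions, DESeq2 called 615/41, 1168/84 and 1510/395 against DMSO, 0/0 from 2 h to 4 h and 86/30 from 4 h to 24 h, nearer to the edgeR counts wherever these had differed, and from 4 h to 24 h it then gave no adjusted p for 5149 regions. From 2 h to 4 h the 0 calls became 2 lower with at least 50 reads and 7/1 at adjusted p under 0.1. From 4 h to 24 h the counts were 40/15 with at least 50 reads, 246/95 at adjusted p under 0.1, 0/0 with DESeq2, 51/19 with limma-voom, 84 lower with weights per group and 77 higher with only the compared groups. Leaving out each library gave 188 to 707 lower and 12 to 82 higher at 2 h, 488 to 1239 and 36 to 137 at 4 h, 708 to 1690 and 130 to 526 at 24 h, and 14 to 145 and 2 to 52 from 4 h to 24 h, always with 0 from 2 h to 4 h; the lone library left in a group was assumed to vary like the others. The lowest counts against DMSO came without DMSO library B, which has more reads in the listed regions (592616 against 253265), and the lowest from 4 h to 24 h without library B of the 24 h group. The HA differences ranged from -0.25 to -0.16, -0.29 to -0.20 and -0.32 to -0.22 with a library left out. They did not pass with the HA summit inside the region (-0.056, -0.0838 and -0.0896). With at least 0.5 of the HA peak inside, which by construction leaves out wide peaks, they turned and passed in the opposite direction (0.13, 0.12 and 0.13). Both of these rules put the remaining regions with an HA peak into the comparison group. The difference at 24 h did not pass with at least 50 reads (-0.12). Matched on mean count they were -0.22, -0.23 and -0.22. Over 824 refits of the named regions none changed sign and 42 no longer passed, mainly with DESeq2 or a library left out. The kept signs were largely set in advance, as the naming rule asked for libraries that separate by group. Some refits left out a library that the region's comparison does not use.

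The column letters were not taken to pair the libraries, as deviations of same-letter libraries from their group means correlated between -0.0091 and 0.042 over 6 pairs of groups. A test between the letters, with the groups in the model, called 25 regions by edgeR, each lower in B. With the letter as a replicate block the counts were 684/78, 1221/133 and 1620/508 against DMSO, 0/0 from 2 h to 4 h and 130/37 from 4 h to 24 h, and the block changed no call of an HA difference. The gene list alternatives were not run, because no annotation of hg19 was at hand.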

Other observations

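The comparisons of peak width, neighbouring regions, clusters and single regions in this part were chosen after seeing the data.

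Among regions with the strongest HA peaks, those under wide peaks lost more BRD4. Within the strongest HA bin, the 1354 regions whose HA peak was wider than the bin's median of 1010 bases had a median log2 change of -0.66 at 24 h, and 46.1% of them were called lower. The 1357 regions under narrower peaks had a median of -0.29, and 22.0% were called lower. Their median HA enrichments were 10.9-fold and 10.4-fold. The difference between wide and narrow was -0.38 and -0.30 in the 24 h libraries. In the weakest bin it was -0.029 and -0.058. Wide-peak regions also held more reads (median 32.8 against 24.9 in the strongest bin), which helps a loss to be called. A strong HA peak did not always go with a called loss, as 1768 of the 2711 regions of the strongest bin (65.2%) were called in neither direction at 24 h. Those regions had a median HA enrichment of 10.3-fold, against 11.4-fold for the lower ones.

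Losses were shared by close neighbours. When a region was lower at 24 h and the next tested region lay within 10 kb, that next region was also lower in 88 of 253 cases (34.8%). The share predicted from the neighbours' own HA bins was 11.6%. That prediction leaves out peak width and read count, and neighbours under the same HA peak were not set apart. The excess is therefore not shown to lie between separate HA peaks. At a gap of 10 to 50 kb the observed and predicted shares were 19.1% and 14.3%, at 50 to 100 kb they were 12.2% and 12.1%, and at 100 to 500 kb they were 14.6% and 12.9%. Log2 changes of adjacent regions at 24 h had a Spearman's rho of 0.42 within 10 kb and 0.15 at 100 to 500 kb, across pairs of regions that are not independent. When regions within 10 kb of each other were joined, 12.6% of the regions in clusters of 3 or more were lower at 24 h, against 9.95% of the regions standing alone, although 14.4% and 18.4% of them lay in the strongest HA bin. Regions in those clusters also held more reads (median 33.1 against 21.1), which helps a loss to be called. Of the 46 regions lower at 24 h that overlapped no HA peak, 19 (41.3%) lay within 5 kb of one, against 538 of the other 2020 tested regions without an HA peak (26.6%; two-sided Fisher's exact test, unadjusted p = 0.042, over regions that are not independent). The median distances to the nearest HA peak were 12547 and 16244 bases. A direct comparison of 24 h with 2 h gave 493 lower and 118 higher regions by edgeR.

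BRD4 counts were high along chromosome 12 between 57 and 59 Mb, where 8 of the 15 regions with the most reads lay. A candidate explanation is a gain in copy number in Rh30, which would raise all regions of the stretch and not single ones. The lower quartile of the mean counts of its 55 regions was 44.4, against 14.8 over all regions, at the 99.9th percentile of 1388 bins of 1 Mb. The test also asked for HA peaks above the 95th percentile in -log10 p, and the 79 HA peaks there had a median of 19.0, at the 84.9th percentile. Their median fold enrichment was 3.70, against 5.12 over all peaks. Together these values leave a copy number gain open, as background reads were not counted here. The control behind the HA values is not given, so whether a gain would raise them is unknown. The median BRD4 change of the stretch at 24 h was 0.17.

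The region with the most reads, on chromosome 1 at 121485009 to 121485409 beside the centromere, held 1711 and 1355 reads in DMSO libraries A and B. It thus took 0.68% and 0.23% of the reads counted in them, and between 0.17% and 0.39% in the dTAG47 libraries.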
